A study of Arabidopsis lyrata subsp. lyrata with 12 samples.

How the data were processed

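RNA was measured in shoots of 6-week-old rosettes of Arabidopsis lyrata ssp. lyrata, the North American rock cress, with 12 arrays in 4 groups of 3. A control group and a group given UV-B were sampled at a mid and at a late time point. Per the labels, UV-B plants received a biologically effective dose of 1.31 kJ per square metre for 4 h, weighted by a plant action spectrum, on top of visible light of 140 micromoles per square metre and second. The labels tie the mid time point to 4 h and the late one to 8 h, but the series description counts these hours from the exposure while the array labels count hours of UV-B, and all arrays carry the same dose text. The times are therefore used here as names of the sampling points, and the dose received by 8 h is open. Nothing in the labels says whether the replicates were separate plants, pools or portions of a single RNA, so every p-value measures the spread between these samples.

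Total RNA was extracted with Trizol and spin columns, labelled with Cy3 by a low-input amplification kit for single-colour arrays, and hybridised to a custom Agilent array, per the labels. Per the file headers, the scanner files hold Cy3 intensity on a linear scale from Feature Extraction 10.7.3.1, after background subtraction by that software and with no scaling between arrays. They also hold the median pixel intensity of each spot and of its local background, per the file headers. The deposited series table holds log2 values. Set against the scanner files over 8110 bright probes, it matched log2 intensity minus each array's 75th percentile minus each probe's median (slopes from 0.999 to 1.00063, r of at least 0.99989). The software the authors used for that step is not given in the sources used here. Because its probes are centred, the series table served as an alternative only, and all values below were computed from the scanner files.

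Each array held 61657 spots for 32863 probes and 32386 gene models, besides control spots. Spots with an outlier mark (165 to 319 per array) were left out, the spots of a probe were averaged on the log2 scale, and the array's 75th percentile was subtracted. A log2 signal of 0 therefore equals the array's own 75th percentile. Probes were kept when at least 0.5 of their spots were well above background, by the scanner software's test, on all 3 arrays of at least 1 group. Where a gene model had several probes, the brightest stood for it, which left 20696 genes to test. On the arrays the 75th percentile of signal ran from 558 to 1294, from 61.0% to 67.3% of spots were well above background, and 0 spots were saturated. The number of arrays limits the precision: the median residual standard deviation was 0.206 on the log2 scale, and the median standard error of a UV-B effect at 4 h was 0.16.

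Gene models are those of the A. lyrata genome annotation used by the array, and 9874 of the tested ones carry an A. thaliana locus in their name. The reference table of genes matched 0 of the probe names, so no genome positions are given. Genes are named by the symbol of that A. thaliana locus where it was in a gene list written before the data were examined, and otherwise by the locus. An A. lyrata gene named this way is the one the array assigns to the locus.

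A limma linear model (limma 3.58.1 in R 4.3.3, files read with data.table, version 1.17.8) was fitted to the 4 groups over all 12 arrays, with moderated variances (11.4 degrees of freedom) and Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05, two-sided. There were 5 comparisons: UV-B against control at 4 h, the same at 8 h, the mean of both, the difference between them (8 h minus 4 h), and 8 h against 4 h in control plants. Errors after a ± sign in the results are limma's standard errors of a log2 change between groups of 3 arrays, unless marked SD. A group in which a gene was well above background on 0 of 3 arrays gave a bound in place of a fold: each of its values was raised to the lowest signal well above background on that array, where it lay under it, before the group means were compared. Such folds are written "at least", and no fold is given when neither group was above background.

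For the 21 gene lists, 264 of 434 members were on the array by their A. thaliana locus and 230 were measured. The lists cover UV-B perception and signalling, phenylpropanoids and flavonoids, DNA repair, antioxidants, the photosynthetic apparatus, photoprotection, jasmonate, salicylate, abscisic acid and cold, ethylene, heat shock, glucosinolates, the circadian clock, growth and auxin, the cell cycle, senescence, markers of root, flower, guard cell and vascular tissue, and reference genes. The 19 lists with at least 3 measured genes were tested against all other genes with camera in limma at a preset correlation of 0.01, adjusted over the lists of a comparison. Alternatives were camera with an estimated correlation and fry, which tests a list against no change and not against other genes. A further 4 groups, chosen after the data were seen, appear in the closing section: small auxin-up RNA genes, shikimate and phenylalanine synthesis, tau class glutathione transferases and plastid genes. Overlap between time points was tested with Fisher's exact test, two-sided.

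The genes to be named were set by a rule set in advance. At 4 h and at 8 h it takes the 8 largest increases and the 8 largest decreases among called genes with a locus and with every UV-B array beyond every control array. From each list it adds up to 4 called members with the smallest adjusted p, and always UVR8, HYH, RUP1, CHS, FLS1 and PHR1. HY5, RUP2, ELIP1, ELIP2 and PR1 were also always to be named, but no probe name carries their locus. For the difference between time points and for time in controls it takes the 5 largest changes in each direction, plus up to 6 called clock genes. Members given as not called, and members of the groups chosen after the data were seen, lie outside this rule and were chosen after their values were seen. Some genes named at 4 h or 8 h are also given for the difference or for time in controls. Which of them are given there was not set by the rule.

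The gene test was tried on simulated log2 values for 20687 genes with changes planted in known genes and 20487 left unchanged. Noise was normal and independent between genes, with a single draw for each comparison. Spot averaging, the filter, the choice of probes and the scaling were not simulated. Far fewer genes were changed than were called in the data, so the shares may differ there. At 4 h, 22.4% of planted 1.5-fold changes, 67.2% of 2-fold and 97.0% of 4-fold changes were called. At 8 h the shares were 22.4%, 70.1% and 93.9%, and for the mean of both times 47.8%, 91.0% and 98.5%. For the difference between time points they were 1.49%, 32.8% and 74.2%, and for time in controls 28.4%, 59.7% and 90.9%. False calls numbered 4, 3, 14, 4 and 6 in the 5 comparisons, which was 8.14% of the calls for the mean of both times and 5.26% for the difference, above the 5% aimed at.

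Alternatives were other scalings (normexp background correction with an offset of 50, quantile normalization, and the 75th percentile over probes bright on every array), no filter or a stricter filter on dim probes, the mean over a gene's probes, a variance trend, array weights, the series table, only the 6 arrays of a comparison, and each array left out in turn. The arrays lay on 2 slides: replicate 1 of every group on slide 2, and replicates 2 and 3 on slide 1, where UV-B and control arrays lay in different columns. Slide was therefore tried as a block, and slide 1 alone was analysed; slide 2 holds 1 array per group and gives no test of its own. The replicate number was also tried as a block. It was not taken to pair samples, because not every pair of arrays with the same number correlated over 0.1 in its deviations from the group means. Between UV-B and control r ran from 0.0105 to 0.223 at 4 h and from 0.0744 to 0.550 at 8 h, and between the control times from -0.397 to 0.142, and 5 of 12 arrays correlated best with arrays of their own number. A correction for array brightness, a fit of array weights gene by gene and normexp on the median signal were added after the data were seen. The planned normexp on the mean signal was not run, because the files hold no such column.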

Results

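Messenger RNA levels were measured in rosette shoots of Arabidopsis lyrata ssp. lyrata under UV-B, to see which genes changed at 4 h and at 8 h against control plants sampled at the same times. The 12 arrays formed 4 groups of 3: control and UV-B at 4 h, and control and UV-B at 8 h. The 75th percentile of signal per array ran from 811 to 1025 in 4 h controls, from 578 to 1012 with UV-B at 4 h, from 615 to 998 in 8 h controls and from 558 to 1294 with UV-B at 8 h. Within groups the arrays correlated across genes with r from 0.981 to 0.996, genes not being independent replicates, and 0 pairs of arrays were identical. The main axis of variation held 46.2% of the variance over genes. For every gene given as risen or fallen at 4 h, at 8 h or with time in controls, each array of the higher group lay above each array of the lower one, except CESA8, AT4G30280 and AT4G30290 at 4 h and PI and NIMIN1 at 8 h.

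Among the genes that rose under UV-B at 4 h were several of the pathway that makes UV-absorbing flavonols. F3PRIMEH (AT5G07990), which hydroxylates flavonoids, rose by 7.94 ± 0.14 on the log2 scale, from a log2 signal of -0.71 ± 0.21 (SD, n = 3) in controls to 7.23 ± 0.07 (SD, n = 3). UGT84A1 (AT4G15480), a hydroxycinnamate glucosyltransferase, was at least 1236-fold higher, its control signal being not well above background (adjusted p = 8.8e-10). Chalcone synthase CHS (AT5G13930), the entry enzyme of the flavonoid pathway, rose by 4.02 ± 0.21 from an already high control signal of 4.23 ± 0.18 (SD, n = 3). The flavonol synthase gene FLS1 (AT5G08640) rose by 5.01 ± 0.12 from -0.85 ± 0.07 (SD, n = 3). At the other end, the auxin-responsive repressor IAA5 (AT1G15580) fell by 4.14 ± 0.19, and the auxin synthesis gene YUC8 (AT4G28720) was at least 14.3-fold lower, its UV-B signal being not well above background (adjusted p = 1.4e-04).

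The other large increases included RUP1 (AT5G52250), a repressor of the UV-B photoreceptor, which rose by 6.19 ± 0.21 from -2.67 ± 0.13 (SD, n = 3). UVR3 (AT3G15620), the photolyase for 6-4 photoproducts, rose by 5.68 ± 0.21 from a control signal well above background on 1 of 3 arrays. AT2G23910 rose by 6.47 ± 0.11, AT4G30470 by 6.10 ± 0.23 and AT5G44110 by 5.56 ± 0.13, and AT1G68250 was at least 99.7-fold higher, with controls not well above background (adjusted p = 2.6e-08). The remaining large decreases were in the small auxin-up RNA genes AT4G13790, at least 47.4-fold lower (adjusted p = 5.9e-07), and AT3G03830, which fell by 4.43 ± 0.30, and in ACS8 (AT4G37770), an ethylene synthesis gene, at least 32.4-fold lower (adjusted p = 2.4e-07). AT3G21330 was at least 9.96-fold lower (adjusted p = 5.6e-06); with UV-B it, ACS8 and AT4G13790 were not well above background. AT4G35720 fell by 4.41 ± 0.19 and AT4G38820 by 3.99 ± 0.26.

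**Figure D1:**
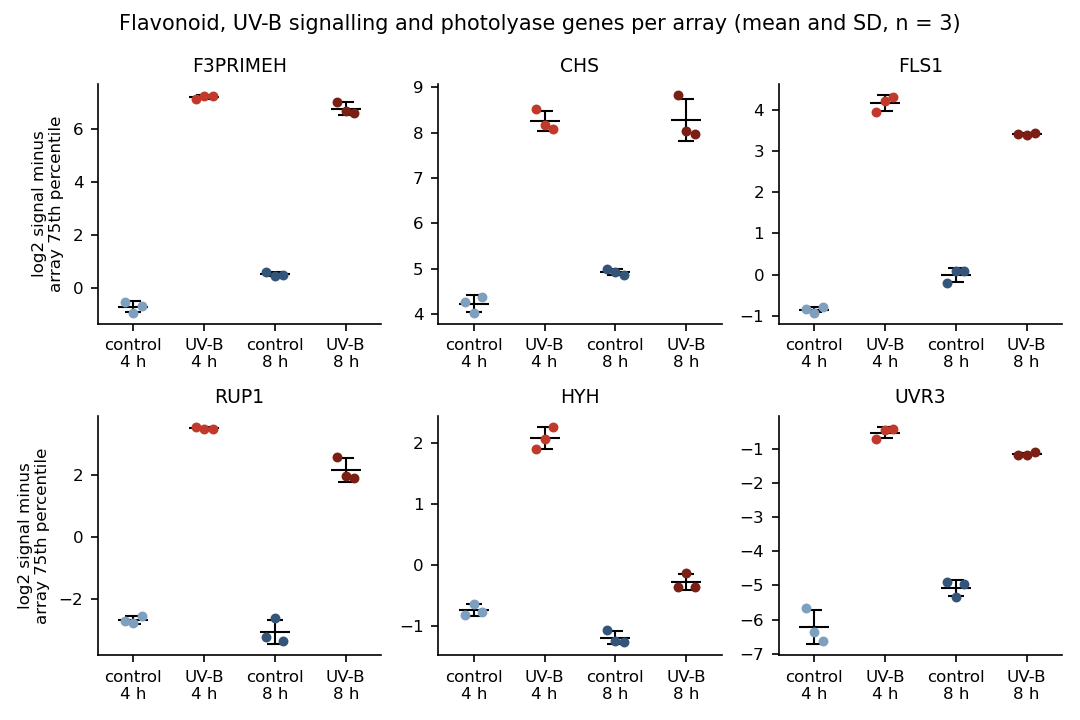
Log2 signal minus the array's 75th percentile for 6 genes on each of the 12 arrays, with the mean and SD of each group of 3 as bars. In all 6 genes the UV-B arrays lie above the control arrays of the same time, from a change of 0.91 for HYH at 8 h to 7.94 for F3PRIMEH at 4 h.

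In the list of phenylpropanoid and flavonoid genes, 17 of 20 rose at 4 h, 0 fell and 3 did not pass, with a median change of 3.80. The counts adjusted over the list alone were the same, 17 and 0. UGT84A2 rose by 5.16 ± 0.12, and F3H went from -2.52 ± 0.08 (SD, n = 3) to 2.28 ± 0.07 (SD, n = 3). By contrast, the regulator EGL3 (0.16), the sinapate ester gene SNG1 (0.11) and PAL3 (-0.02) did not pass. The list was called as raised (camera adjusted p = 3.7e-17), also with an estimated correlation (adjusted p = 0.0015). Of the 9 genes of UV-B perception and signalling, 6 rose and 2 fell (7 and 2 adjusted over the list alone). This list had a median of 0.72 and a camera adjusted p of 0.0056 (adjusted p = 0.062 with an estimated correlation). HYH, a bZIP transcription factor of light signalling, rose by 2.82 ± 0.12 from -0.74 ± 0.10 (SD, n = 3) and BBX31 by 2.57 ± 0.15, while BBX21 fell by 1.80 ± 0.10. The photoreceptor gene UVR8 itself fell by 0.40 ± 0.12 from 2.43 ± 0.19 (SD, n = 3; adjusted p = 0.020). This call ended within slide 1 (-0.31), without control replicate 1 (-0.29) or UV-B replicate 3 (-0.36) at 4 h, and with no filter on dim probes (-0.40).

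Antioxidant genes were also raised as a list at 4 h, with 9 of 16 higher, 1 lower and 6 not passing (10 and 2 adjusted over the list alone). Their median was 0.74 and camera gave an adjusted p of 0.0098 (adjusted p = 0.285 with an estimated correlation). The catalase CAT2 rose by 2.96 ± 0.16, the tocopherol cyclase VTE1 by 1.43 ± 0.15 and the ascorbate synthesis gene VTC2 by 1.33 ± 0.16. Clock genes rose in 6 of 12 cases with 0 lower (6 and 0 adjusted over the list alone). The clock median was 0.43 and the camera adjusted p 0.0059 (adjusted p = 0.085 with an estimated correlation). FKF1 rose by 2.90 ± 0.24, TOC1 by 2.07 ± 0.25 and ELF4 by 1.70 ± 0.16, which are transcripts of the evening, and RVE8, a transcript of the morning, by 0.91 ± 0.14. Among 9 DNA repair genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone), median 0.14, and the list was not called (camera adjusted p = 0.099). Those 3 were UVR3, the photolyase PHR1, up by 2.19 ± 0.11 from -0.09 ± 0.10 (SD, n = 3), and DDB1B, up by 0.40 ± 0.12. The call of DDB1B ended under the percentile over bright probes (0.32) and without control replicate 3 (0.33) or UV-B replicate 2 (0.34) or 3 (0.38) at 4 h.

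Several smaller groups rose in part at 4 h without a call for the list. In photoprotection, 2 of 6 rose and 0 fell (3 and 0 adjusted over the list alone), with a median of 0.32 and an adjusted p of 0.11. They were the carotene hydroxylase BCH1 by 2.73 ± 0.22 and the protease FTSH5 by 0.98 ± 0.15. Of 13 heat shock genes 6 rose and 0 fell (6 and 1 adjusted over the list alone; median 0.45, adjusted p = 0.15), such as HSP101 by 0.71 ± 0.11 and HSFA2 by 0.93 ± 0.23. Abscisic acid and cold genes went both ways, with 4 of 16 higher and 4 lower (4 and 5 adjusted over the list alone). DREB2A was at least 22.0-fold higher, its controls being not well above background (adjusted p = 1.3e-07), COR15B rose by 1.53 ± 0.11 and RD29B fell by 1.60 ± 0.35. Their median was -0.20 while the mean was 0.17 and camera pointed up (adjusted p = 0.74). In the senescence list 2 of 7 rose and 3 fell (3 and 3 adjusted over the list alone; median -0.30, adjusted p = 0.74), with SGR1 at 1.26 ± 0.19 and SEN1 at -1.94 ± 0.31.

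Genes of growth and auxin were lower as a list at 4 h, 7 of 16 falling and 2 rising (8 and 2 adjusted over the list alone). For this list the median was -0.51 and the camera adjusted p 0.0020 (adjusted p = 0.285 with an estimated correlation). HAT2, an auxin-responsive homeobox gene, fell by 3.46 ± 0.13, GA20OX1 of gibberellin synthesis by 2.78 ± 0.17 and IAA19 by 2.53 ± 0.17. Ethylene genes fell in 7 of 11 cases and rose in 0 (7 and 0 adjusted over the list alone), with a median of -0.64, or -0.63 with bounded genes at their bound. Camera called the ethylene list (adjusted p = 9.2e-04), a call that held with an estimated correlation (adjusted p = 0.049). CTR1, a negative regulator of the ethylene response, fell by 1.63 ± 0.10 and the F-box gene EBF2, which acts the same way, by 1.27 ± 0.14. Jasmonate genes fell in 6 of 16 cases and rose in 1 (6 and 1 adjusted over the list alone). The jasmonate median was -0.33 and the camera adjusted p 0.036 (adjusted p = 0.497 with an estimated correlation). The sulfotransferase ST2A fell by 2.41 ± 0.13, the lipoxygenase LOX3 by 1.82 ± 0.22 and OPR3 by 1.13 ± 0.24. The jasmonate call ended without control replicate 1 (adjusted p = 0.085) or UV-B replicate 2 (0.065) or 3 (0.083) at 4 h.

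Photosynthesis genes were lower in 8 of 28 cases and higher in 0 at 4 h (8 and 0 adjusted over the list alone). With a median of -0.34 they had a camera adjusted p of 0.0083 (adjusted p = 0.681 with an estimated correlation). The antenna genes LHCB4.2 and LHCB3 fell by 1.64 ± 0.24 and 0.81 ± 0.12, and PSAF of photosystem I by 1.03 ± 0.18. The rotation test fry, which asks whether a list changed at all and makes no comparison with other genes, did not call it (adjusted p = 0.097). Salicylate and defence genes fell in 4 of 8 cases and rose in 0 (4 and 0 adjusted over the list alone; median -0.70, adjusted p = 0.093). WRKY70 fell by 1.47 ± 0.18, EDS1 by 1.28 ± 0.18 and ICS1 by 0.96 ± 0.13. The calls of WRKY70 (-0.27) and ICS1 (-0.54) ended under normexp. Of 10 glucosinolate genes 1 fell, MYB51 by 0.80 ± 0.13, and 0 rose (1 and 0 adjusted over the list alone; median -0.12, adjusted p = 0.55), and under normexp MYB51 (-0.40) was no longer called. Among 14 cell cycle genes, 0 were called either way (0 and 0 adjusted over the list alone; median 0.16, adjusted p = 0.55).

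Reference genes, often taken as stable, were lower too: 5 of 8 fell at 4 h and 0 rose (5 and 0 adjusted over the list alone). Their median of -0.47 stayed negative under each scaling tried, and the camera adjusted p was 0.018 (adjusted p = 0.285 with an estimated correlation). The actin genes ACT8 and ACT7 fell by 1.23 ± 0.13 and 0.75 ± 0.13 and UBQ10 by 0.90 ± 0.20. Vascular markers fell in 3 of 6 cases (4 adjusted over the list alone; median -0.38, adjusted p = 0.10), CESA4 by 0.52 ± 0.12 and CESA8 by 0.53 ± 0.18. Under normexp CESA4 was not called (-0.33) and CESA8 reversed its sign (0.02). Of 3 guard cell markers KAT1 fell by 0.75 ± 0.20, again not under normexp (-0.39). No guard cell marker rose (1 lower and 0 higher adjusted over the list alone; median -0.33, adjusted p = 0.55). The single root marker WER was at least 2.18-fold lower, with UV-B not well above background (adjusted p = 0.0064), but had the opposite sign under normexp (0.01). Of 2 flower markers SEP3 fell by 0.59 ± 0.17 (1 adjusted over the list alone), not under normexp (-0.29) or without control replicate 2 (-0.51) or 3 (-0.53) or UV-B replicate 3 (-0.47) at 4 h. Normexp also turned the median of this pair from -0.29 to 0.02.

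At 4 h limma called 8289 of 20696 genes, 4007 higher and 4282 lower, of which 1359 and 1055 changed at least 2-fold, together 2414 against 1505 under normexp. The split by direction depends on the scaling: 48.3% were higher, against 56.3% under normexp, 44.2% under quantile normalization and 40.4% under the percentile over bright probes. The median change of all genes was 0.00, and 0.10, -0.04 and -0.08 under these scalings. Of the called genes, 158 (1.91%) had 1 group with 0 arrays well above background, so their folds are bounds. With slide as a block 8651 genes were called, and within slide 1 6847. The positions of the UV-B and control arrays on slide 1 differed by column.

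At 8 h several flavonoid genes were again raised. F3PRIMEH rose by 6.27 ± 0.14, from 0.52 ± 0.08 (SD, n = 3) in controls to 6.79 ± 0.23 (SD, n = 3), and RUP1 by 5.22 ± 0.21 from -3.05 ± 0.39 (SD, n = 3). UGT84A1 was at least 222-fold higher, with controls not well above background (adjusted p = 1.5e-08). CHS rose by 3.35 ± 0.21 from 4.93 ± 0.07 (SD, n = 3) and FLS1 by 3.41 ± 0.12 from -0.01 ± 0.16 (SD, n = 3). Among the genes that fell were the small auxin-up RNA genes AT3G03830, by 4.22 ± 0.30, AT4G13790, by 3.84 ± 0.39, and AT4G34770, by 3.68 ± 0.41.

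Other large increases at 8 h were AT4G30470, up by 6.17 ± 0.23 from a control signal well above background on 1 of 3 arrays, and AT1G68250, at least 47.7-fold higher (adjusted p = 2.0e-07). AT4G22110 was at least 19.3-fold higher (adjusted p = 3.2e-08), AT5G51950 at least 14.1-fold (adjusted p = 8.2e-07) and AT5G06650 at least 9.74-fold (adjusted p = 1.7e-06). The controls of these last 4 genes were not well above background. The remaining large decreases were in AT4G14819 (-4.96 ± 0.17), AT1G70270 (-4.04 ± 0.21), AT4G38820 (-3.94 ± 0.26), AT4G16515 (-3.90 ± 0.21) and AT5G19190 (-3.68 ± 0.34).

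The phenylpropanoid and flavonoid list held 17 genes that rose at 8 h, 0 that fell and 3 that did not pass (17 and 0 adjusted over the list alone). The median was 2.86 and the camera adjusted p 4.9e-24, a call that held with an estimated correlation (adjusted p = 4.5e-04). F3H rose by 3.72 ± 0.13 and UGT84A2 by 3.20 ± 0.12. In UV-B perception and signalling 6 of 9 rose and 2 fell (7 and 2 adjusted over the list alone). Here the median was 0.74 and the camera adjusted p 0.0019 (adjusted p = 0.059 with an estimated correlation). HYH rose by 0.91 ± 0.12 from -1.19 ± 0.11 (SD, n = 3) and BBX31 by 2.18 ± 0.15, while BBX21 fell by 1.29 ± 0.10. UVR8 fell by 0.52 ± 0.12 from 2.77 ± 0.14 (SD, n = 3; adjusted p = 0.010), a change of -0.52 that was not called within slide 1.

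DNA repair genes rose in 3 of 9 cases at 8 h and fell in 0 (3 and 0 adjusted over the list alone). Around a median of 0.07 the camera adjusted p was 0.017 (adjusted p = 0.158 with an estimated correlation, and 0.051 with the brightness covariate). UVR3 rose by 3.91 ± 0.21 and PHR1 by 1.21 ± 0.11 from -0.34 ± 0.11 (SD, n = 3), and DDB1B by 0.49 ± 0.12, not called within slide 1 (0.46). Photoprotection genes rose in 4 of 6 cases and fell in 0 (4 and 0 adjusted over the list alone). Photoprotection had a median of 0.71 and a camera adjusted p of 0.028 (adjusted p = 0.125 with an estimated correlation, and 0.096 within slide 1). FTSH5 rose by 1.23 ± 0.15 and ZEP of the xanthophyll cycle by 0.67 ± 0.13. Clock genes rose in 4 of 12 cases and fell in 0 (6 and 0 adjusted over the list alone). In this list the median was 0.47 and the camera adjusted p 0.0040 (adjusted p = 0.078 with an estimated correlation). RVE8 rose by 1.19 ± 0.14 and LNK2 by 0.81 ± 0.15; normexp ended the call of RVE8 (0.26), and slide 1 alone that of LNK2 (0.67). Antioxidant genes went both ways, 5 of 16 higher and 5 lower (7 and 7 adjusted over the list alone; median 0.29, adjusted p = 0.33). GSTF6 rose by 1.60 ± 0.20 and AOX1A by 1.12 ± 0.14, and VTC1 fell by 0.94 ± 0.12.

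Genes of growth and auxin fell in 11 of 16 cases at 8 h and rose in 1 (12 and 1 adjusted over the list alone). The growth median was -1.13, or -1.10 with the bounded gene at its bound, and the camera adjusted p 1.1e-06 (adjusted p = 0.158 with an estimated correlation). IAA5 fell by 3.53 ± 0.19, IAA19 by 2.76 ± 0.17 and HAT2 by 1.59 ± 0.13. Photosynthesis genes fell in 14 of 28 cases and rose in 0 (19 and 0 adjusted over the list alone). At a median of -0.66 the camera adjusted p was 2.6e-06 (adjusted p = 0.513 with an estimated correlation). LHCB1.4 fell by 1.95 ± 0.29, LHCB4.2 by 1.24 ± 0.24 and LHCB6 by 1.11 ± 0.20. Ethylene genes fell in 6 of 11 cases and rose in 0 (6 and 0 adjusted over the list alone). Their median was -0.59, or -0.55 without ACS8, which was above background in neither group. The ethylene list had a camera adjusted p of 0.0060 (adjusted p = 0.078 with an estimated correlation). CTR1 fell by 0.59 ± 0.10 and EBF2 by 0.81 ± 0.14. Of the 16 abscisic acid and cold genes 8 fell and 2 rose (10 and 2 adjusted over the list alone). This gave a median of -0.58 and a camera adjusted p of 0.033 (adjusted p = 0.396 with an estimated correlation). CBF2 fell by 1.67 ± 0.25 and ABI2 by 0.86 ± 0.16, while DREB2A rose by 1.97 ± 0.24. That call ended under quantile normalization (adjusted p = 0.063) and without control replicate 3 (0.0996) or UV-B replicate 2 (0.067) at 8 h.

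Several other lists were not called at 8 h. Jasmonate genes fell in 2 of 16 cases and rose in 1 (2 and 1 adjusted over the list alone; median -0.25, adjusted p = 0.50), ST2A by 0.83 ± 0.13. In salicylate and defence 2 of 8 fell and 0 rose (3 and 0 adjusted over the list alone; median -0.04, or 0.04 under the percentile over bright probes, adjusted p = 0.48). ICS1 fell by 0.55 ± 0.13 and NIMIN1 by 0.92 ± 0.24, but under normexp neither was called (-0.38 and -0.67). Glucosinolate genes fell in 2 of 10 cases and rose in 0 (2 and 0 adjusted over the list alone; median -0.34, adjusted p = 0.11), CYP83A1 by 0.73 ± 0.23, a call that ended within slide 1 (-0.73) and in 5 other settings. Heat shock genes fell in 1 of 13 cases, HSP23.6 by 0.71 ± 0.16, and rose in 0 (1 and 0 adjusted over the list alone). With a median of -0.01 and a mean of -0.06 camera pointed up (adjusted p = 0.84), and the median turned to 0.0036 under quantile normalization and 0.07 under the percentile over bright probes. Of 14 cell cycle genes 1 fell, the replication licensing gene CDT1A by 0.55 ± 0.14, and 0 rose (1 and 0 adjusted over the list alone; median -0.17, adjusted p = 0.39), a call that ended within slide 1 (-0.55). Senescence genes rose in 1 of 7 cases and fell in 2 (1 and 2 adjusted over the list alone), with SWEET15 at -1.79 ± 0.20 and SGR1 at 0.95 ± 0.19. The list median was 0.04 against a mean of -0.20 and a camera direction of down (adjusted p = 0.96).

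Reference genes fell in 2 of 8 cases at 8 h and rose in 0 (2 and 0 adjusted over the list alone; median -0.19, negative under each scaling tried, adjusted p = 0.15). ACT7 fell by 0.52 ± 0.13 and ACT8 by 0.49 ± 0.13. Neither call held without UV-B replicate 3 at 8 h (-0.45 for both). Vascular markers fell in 1 of 6 cases, XCP1 by 0.48 ± 0.14, and rose in 0 (1 and 0 adjusted over the list alone). The vascular median was 0.02, or -0.01 under normexp, against a mean of -0.05 and a camera direction of down (adjusted p = 0.96). Of the 3 guard cell markers GASA9 fell by 0.69 ± 0.21 and 0 rose (1 and 0 adjusted over the list alone; median -0.26, adjusted p = 0.50), and XCP1 (-0.40) and GASA9 (-0.83) were not called within slide 1. The flower markers SEP3 and PI fell by 0.78 ± 0.17 and 0.81 ± 0.27 (2 of 2 adjusted over the list alone), PI being not called under any of the 3 other scalings (-0.38, -0.77 and -0.74). The root marker WER, above background in neither group, was not called over all genes and 1 was lower adjusted over the list alone.

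At 8 h limma called 4996 genes, 2187 higher and 2809 lower, of which 654 and 649 changed at least 2-fold, together 1303 against 711 under normexp. This split reverses with the scaling: 43.8% were higher, against 53.2% under the percentile over bright probes, which also turned the median change of all genes from -0.06 to 0.01. For 123 of them (2.46%) the fold is a bound. The slide block gave 5493 genes and slide 1 alone 3431. The count rose to 8807 with array weights, and to 8132 with weights fitted gene by gene.

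**Figure D2:**
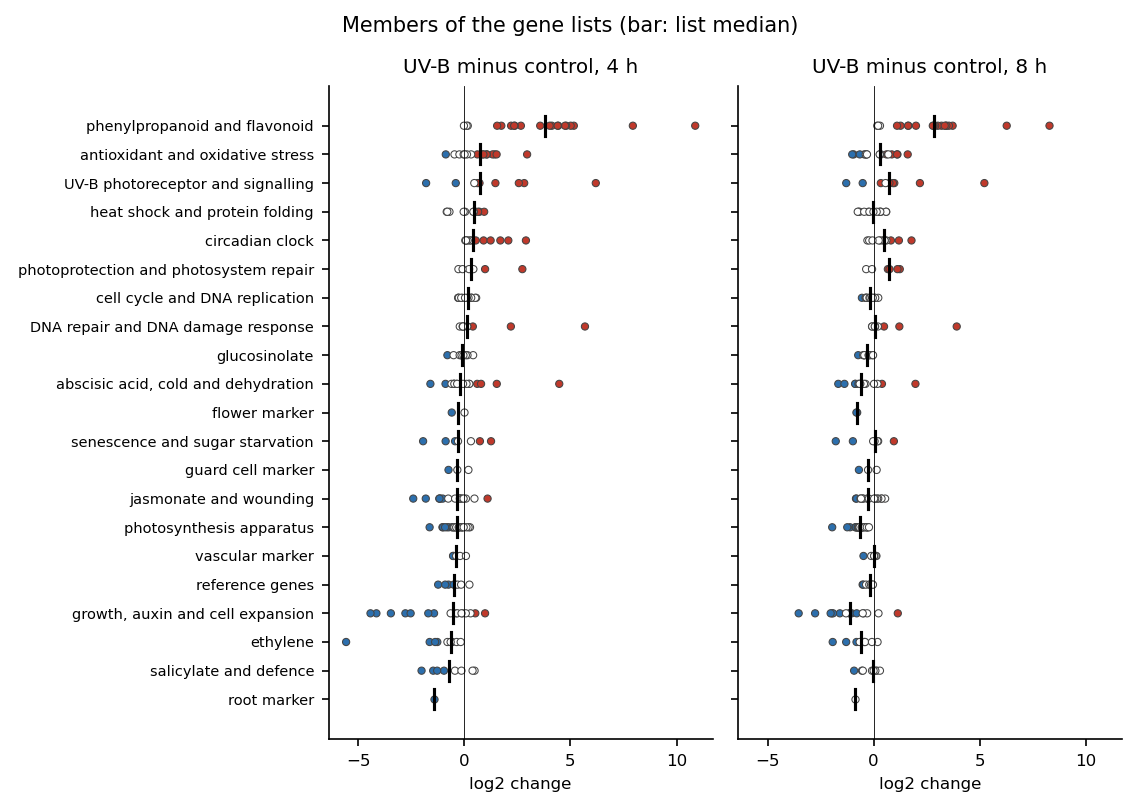
Log2 changes under UV-B of the measured members of the 21 gene lists at 4 h and at 8 h, with filled points for called genes, red if higher and blue if lower, open points for the others and a bar at the list median. The median of the phenylpropanoid and flavonoid list lies at 3.80 and 2.86, and that of growth and auxin genes at -0.51 and -1.13. Medians that change sign under other scalings are those of heat shock and salicylate at 8 h (0.07 and 0.04 under the percentile over bright probes), and of root and flower markers at 4 h (0.01 and 0.02) and vascular markers at 8 h (-0.01) under normexp, and folds of genes not above background are fitted values.

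Averaged over both time points, UV-B changed 9075 genes by limma, 4113 higher and 4962 lower, with 1532 of them changing at least 2-fold (880 under normexp) and a median change of all genes of -0.05. Many genes were called in the same direction at both times. Of the genes higher at 8 h, 1569 (71.7%) were also higher at 4 h, where 423 would be shared if the calls were independent (odds ratio 16.7, 95% confidence interval 15.1 to 18.6, Fisher's exact test). Of those lower at 8 h, 1533 (54.6%) were also lower at 4 h, against 581 (odds ratio 6.61, interval 6.07 to 7.21). The log10 of p was -721 and -411, but genes are not independent replicates and the intervals do not cover that. Both calls also used the same variance estimate for each gene, which can make shared calls more frequent than under independence. Of 3200 genes called at both times 98 had opposite directions, 59 higher then lower and 39 lower then higher. Across genes, which are not independent replicates, the changes at 8 h and 4 h correlated with Pearson's r of 0.693 and Spearman's rho of 0.512. With slide as a block the mean effect gave 9514 genes, and slide 1 alone 7945.

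The response differed with time mostly by being smaller at 8 h. Several flavonoid genes rose less: UGT84A2 by a difference (8 h minus 4 h) of -1.96 ± 0.16, F3PRIMEH by -1.67 ± 0.20 and FLS1 by -1.60 ± 0.17. HYH differed by -1.91 ± 0.18 and the catalase CAT2 by -2.68 ± 0.22, from 2.96 at 4 h to 0.28 at 8 h. Among the clock genes FKF1 differed by -2.67 ± 0.34, from 2.90 to 0.24, TOC1 by -1.55 ± 0.35 and ELF4 by -1.39 ± 0.23, while LNK2 differed by 0.77 ± 0.21. TOC1 (adjusted p = 0.021) lost its call in 5 settings, among them each of UV-B replicates 2 (-1.38) and 3 (-1.38) at 4 h left out. ELF4 (adjusted p = 0.0054) lost it within slide 1 (-1.19), and LNK2 (adjusted p = 0.043) in 15 settings, such as slide 1 alone (0.70).

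A few genes turned from one direction to the other. AT4G30280 and AT4G30290, genes for cell wall xyloglucan enzymes, were higher at 4 h (1.78 and 0.84) and lower at 8 h (-1.80 and -2.16), differences of -3.57 ± 0.62 and -3.01 ± 0.42. AT3G19030 went from 1.03 to -2.11, a difference of -3.14 ± 0.30, and AT1G61360 from -1.02 to a higher signal with UV-B at 8 h, a difference of 2.52 ± 0.31 that was not called under normexp (0.59). By contrast, AT4G18540, AT3G14395 and AT4G16740 were called at 4 h but not at 8 h (limma adjusted p = 0.32, 0.39 and 0.52). AT4G18540 differed by 2.60 ± 0.19, from -2.40 to 0.20, and AT3G14395 by -2.95 ± 0.52, from 2.48 to -0.47. The difference of AT4G16740, -3.14 ± 0.88 (adjusted p = 0.045), was not called in 12 settings, such as quantile normalization (-3.15). The largest positive differences were those of AT3G21330 (4.35 ± 0.57), ACS8 (4.28 ± 0.46) and YUC8 (3.12 ± 0.84), which involve groups not well above background and bound no fold. Under normexp none of these 3 was called (0.91, 1.49 and 1.02), and YUC8 (adjusted p = 0.040) lost its call in 11 settings.

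As lists, phenylpropanoid and flavonoid genes had the smaller effect at 8 h, with 11 of 20 called lower and 0 higher (11 and 0 adjusted over the list alone). The median difference was -0.97 and the camera adjusted p 7.3e-06 (adjusted p = 0.053 with an estimated correlation). Abscisic acid and cold genes were called lower in 5 of 16 cases (7 adjusted over the list alone), with a median of -0.39. Camera gave them an adjusted p of 0.0072 (adjusted p = 0.383 with an estimated correlation, and 0.063 within slide 1). Among them COR15B was at -1.14 ± 0.16. Antioxidant genes were lower in 3 of 16 cases (3 adjusted over the list alone), with a median of -0.24 that became 0.05 under quantile normalization. The camera adjusted p was 0.047 (adjusted p = 0.383 with an estimated correlation). Ethylene genes were higher in 2 of 11 cases (2 adjusted over the list alone), median 0.47, camera adjusted p = 0.047 (adjusted p = 0.311 with an estimated correlation). Both of the last calls ended with slide as a block (adjusted p = 0.057 for each), within slide 1 (0.063 and 0.122) and with the replicate number as a block (0.052 for each). The antioxidant call also ended with the brightness covariate (0.056) and under quantile normalization (0.517), and without control replicate 2 (0.080) or UV-B replicate 1 (0.068) or 2 (0.055) at 4 h, or control replicate 2 (0.058) or 3 (0.080) or UV-B replicate 2 (0.067) at 8 h. The ethylene call ended without control replicate 1 (0.069) or 2 (0.057) or UV-B replicate 3 (0.061) at 4 h, or control replicate 1 (0.052), 2 (0.056) or 3 (0.058) or UV-B replicate 1 (0.067) at 8 h.

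The other lists had no call for the difference. UV-B signalling had 1 gene lower and 0 higher (4 and 1 adjusted over the list alone; median -0.38, or 0.06 under quantile normalization, adjusted p = 0.16), and jasmonate 2 higher (4 adjusted over the list alone; median 0.30, adjusted p = 0.052). DNA repair had 2 lower (2 adjusted over the list alone), with a median of 0.06, or -0.10 under normexp, against a mean of -0.25 and a camera direction of down (adjusted p = 0.62). Photoprotection had 2 lower (1 higher and 2 lower adjusted over the list alone), with a median of 0.23 and camera up against a mean of -0.11 (adjusted p = 0.89). Growth and auxin had 3 higher and 2 lower (3 and 3 adjusted over the list alone), with a median of -0.28 against a mean of 0.07 and camera up (adjusted p = 0.98). Clock genes had 1 higher and 3 lower (1 and 3 adjusted over the list alone; median -0.05, but 0.01 under quantile normalization and 0.10 under the percentile over bright probes, adjusted p = 0.65). Salicylate genes had 2 higher (3 adjusted over the list alone; median 0.35, or -0.14 under normexp, adjusted p = 0.16). Heat shock had 1 lower (4 adjusted over the list alone; median -0.14, or 0.01 under the percentile over bright probes, adjusted p = 0.26), and reference genes 1 higher (1 adjusted over the list alone; median 0.27, adjusted p = 0.12). Senescence had 1 higher and 1 lower (1 and 1 adjusted over the list alone), with a median of -0.10, or 0.21 under quantile normalization and 0.06 under the percentile over bright probes, a mean of -0.02 and camera up (adjusted p = 0.84). No photosynthesis gene was called (median -0.35, or 0.05 under quantile normalization, adjusted p = 0.27), and no cell cycle gene (median -0.23, adjusted p = 0.20) or glucosinolate gene (median -0.27, adjusted p = 0.62), also adjusted over the list alone. Vascular markers had 0 called (1 higher adjusted over the list alone; median 0.30, adjusted p = 0.15). Guard cell markers had 0 called (1 higher adjusted over the list alone), with a median of -0.37 against a mean of 0.02 and camera up (adjusted p = 0.98). The flower markers (median -0.50) and the root marker (0.53, or -0.29 under normexp) were not called, also adjusted over the list alone.

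For the difference limma called 2076 genes, 934 positive and 1142 negative, of which 1689 (81.4%) had the smaller change at 8 h and 387 the larger, and the slope of the 8 h changes on those at 4 h across genes was 0.538. The split by sign depends on the scaling: 45.0% were positive, against 57.3% under quantile normalization, 68.3% under the percentile over bright probes and 31.4% under normexp. The median difference of all genes was -0.07, against 0.08 under the percentile over bright probes and -0.18 under normexp. The count was 2434 with slide as a block, 465 within slide 1 and 6912 with array weights, and ran from 848 without control replicate 2 at 4 h to 3158 without control replicate 3 at 8 h.

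**Figure D3:**
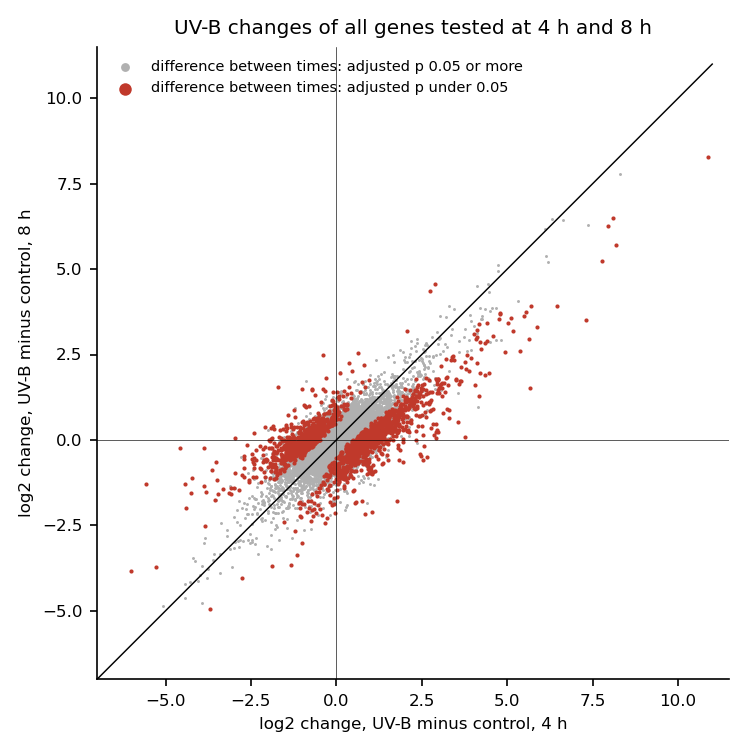
Log2 change under UV-B at 8 h against that at 4 h for the 20696 genes tested, with the 2076 genes whose effects differed in red and a line of equal change. Of the red genes 81.4% have the smaller change at 8 h, and changes of genes not above background are fitted values.

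Control plants also differed between the times, which gives the background for the time comparison. AT3G20810, the histone demethylase gene also named JMJ30, rose from 4 h to 8 h by 5.27 ± 0.16. LUX rose by 4.62 ± 0.21 from a 4 h signal well above background on 1 of 3 arrays. FKF1 rose by 4.51 ± 0.24 from -0.70 ± 0.27 (SD, n = 3) to 3.81 ± 0.03 (SD, n = 3). ELF4 rose by 3.88 ± 0.16 and AT5G37260, a MYB-like clock gene, by 4.17 ± 0.36. The morning gene PRR9 was at least 42.7-fold lower at 8 h, not well above background there (adjusted p = 7.3e-07). RVE8 fell by 3.01 ± 0.14 and LNK2 went from -0.22 ± 0.18 (SD, n = 3) to -3.32 ± 0.21 (SD, n = 3). ACS8 (at least 22.4-fold, adjusted p = 4.1e-06) and AT3G21330 (at least 8.65-fold, adjusted p = 3.5e-05) were lower at 8 h with signals not well above background, AT1G18330 fell by 4.15 ± 0.14 and AT1G73870 by 4.02 ± 0.20.

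Of the 12 clock genes 6 rose and 4 fell with time in controls (6 and 4 adjusted over the list alone), which gave a median of 0.72 and no call (camera adjusted p = 0.28). Phenylpropanoid and flavonoid genes rose in 7 of 20 cases and fell in 0 (9 and 0 adjusted over the list alone), with a median of 0.49, or 0.47 with a gene not above background at either time left out. Camera called the rise (adjusted p = 0.010, but adjusted p = 0.163 with an estimated correlation). Photoprotection genes fell in 2 of 6 cases (3 adjusted over the list alone; median -0.43, camera adjusted p = 0.010, adjusted p = 0.143 with an estimated correlation). UV-B signalling genes fell in 5 of 9 cases with 1 rising (5 and 2 adjusted over the list alone; median -0.45, camera adjusted p = 0.030, adjusted p = 0.163 with an estimated correlation). Growth and auxin genes fell in 7 of 16 cases and rose in 1 (7 and 1 adjusted over the list alone; median -0.16), and photosynthesis genes fell in 4 of 28 (4 adjusted over the list alone; median -0.11). Each of these lists had a camera adjusted p of 0.048 (adjusted p = 0.587 and 0.729 with an estimated correlation). Left out in turn, control replicate 3 at 8 h ended 4 of these calls: phenylpropanoids (adjusted p = 0.054), UV-B signalling (0.072), growth (0.199) and photosynthesis (0.331), the last also lost within slide 1 (0.065) and by fry (0.245). Growth and photosynthesis also lost their calls without control replicate 1 (0.056 and 0.094) or 3 (0.152 and 0.215) at 4 h.

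No other list was called with time in controls. Of 16 abscisic acid and cold genes 7 rose and 4 fell (7 and 4 adjusted over the list alone; median 0.37, adjusted p = 0.28). Of 16 antioxidant genes 3 rose and 2 fell (4 and 2 adjusted over the list alone; median 0.15, adjusted p = 0.42). In the ethylene list 3 of 11 rose and 2 fell (5 and 4 adjusted over the list alone), with a median of 0.41 and camera up against a mean of -0.04 (adjusted p = 0.88). Cell cycle genes rose in 2 of 14 cases (2 adjusted over the list alone; median 0.27, adjusted p = 0.062). Glucosinolate genes fell in 5 of 10 and rose in 1 (5 and 1 adjusted over the list alone; median -0.36, adjusted p = 0.062). Jasmonate genes fell in 4 of 16, among them ST2A by 0.75 ± 0.13 (4 adjusted over the list alone; median -0.24, adjusted p = 0.062). Heat shock genes fell in 4 of 13 and rose in 1 (5 and 1 adjusted over the list alone; median -0.33, adjusted p = 0.23). Salicylate genes rose in 2 of 8 and fell in 1 (3 and 1 adjusted over the list alone; median 0.25, adjusted p = 0.42). Of 7 senescence genes 1 rose and 2 fell (2 and 3 adjusted over the list alone; median -0.18, adjusted p = 0.28). Of 9 DNA repair genes 1 rose, UVR3 by 1.15 ± 0.21 (1 adjusted over the list alone), with a median of -0.06 and camera down against a mean of 0.05 (adjusted p = 0.89). Reference genes rose in 1 of 8 cases (0 adjusted over the list alone; median 0.11, or -0.10 under quantile normalization, adjusted p = 0.89).

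Among tissue markers 1 of 6 vascular ones fell in controls (2 adjusted over the list alone; median -0.16, adjusted p = 0.24). Of 3 guard cell markers KAT1 fell by 0.69 ± 0.20 (1 adjusted over the list alone), with a median of 0.15 against a mean of -0.10 and camera down (adjusted p = 0.88). Neither flower marker was called, also adjusted over the list alone (median 0.15). The root marker WER was at least 2.30-fold lower at 8 h, where it was not well above background (adjusted p = 0.017; 1 lower adjusted over the list alone).

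With time in controls limma called 3691 genes, 2028 higher and 1663 lower at 8 h, of which 484 and 532 changed at least 2-fold (together 1016, or 590 under normexp), with a bound in place of a fold for 97 (2.63%). The split by direction reverses here too: 54.9% were higher, against 46.3% under the percentile over bright probes. The median of all genes was 0.02, but -0.05 under that scaling and -0.01 under quantile normalization. With slide as a block 4059 were called and within slide 1 1718. On slide 1 the 4 h controls lay in rows 1 and 2 and the 8 h controls in rows 3 and 4. On slide 2 they lay in row 3 at 4 h and in row 4 at 8 h. An effect of the row on this comparison was not tested. The count was 7755 with array weights, 2346 without control replicate 1 at 4 h, 2022 without control replicate 2 at 4 h, 2386 without control replicate 2 at 8 h and 2241 with no filter on dim probes.

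**Figure D4:**
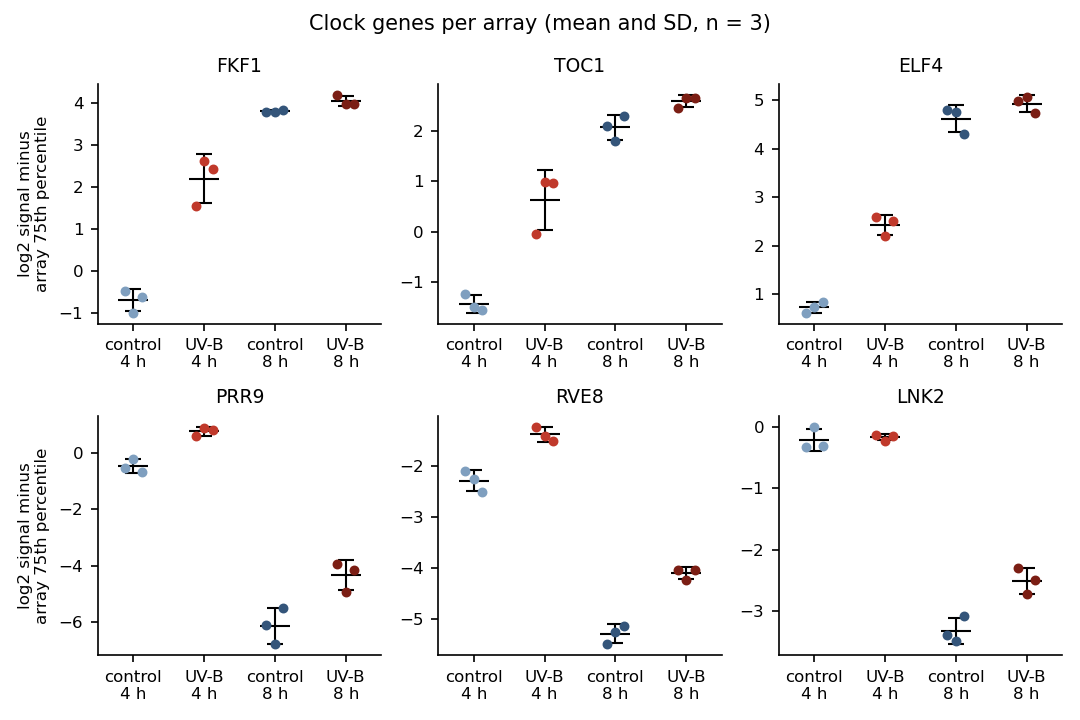
Log2 signal minus the array's 75th percentile for 6 clock genes on each of the 12 arrays, with the mean and SD of each group of 3 as bars. In controls FKF1, TOC1 and ELF4 rose with time (by 4.51, 3.51 and 3.88) and PRR9, RVE8 and LNK2 fell, PRR9 to a signal not well above background; at 4 h UV-B arrays lie above controls except for LNK2 (0.04).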

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

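Of the tests in this part, the brightness covariate for the UV-B effects and the reading of the clock genes that fell with time were chosen after the result was seen. The results given here are those whose UV-B effect differed between 4 h and 8 h by the interaction term (8 h minus 4 h), tested with limma for genes and camera for lists. They comprise 2076 genes and 4 lists: phenylpropanoids and flavonoids (adjusted p = 7.3e-06), abscisic acid and cold (0.0072), antioxidants (0.047) and ethylene (0.047). With an estimated correlation the list values were 0.053, 0.383, 0.383 and 0.311.

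Among named genes that UV-B raised at 4 h, the difference was negative for the flavonoid genes UGT84A1 (-2.59), F3PRIMEH (-1.67), UGT84A2 (-1.96), FLS1 (-1.60) and F3H (-1.08). It was negative too for AT2G23910 (-2.54), AT5G44110 (-1.81), the photolyase genes UVR3 (-1.77) and PHR1 (-0.98), and HYH (-1.91). In abscisic acid and cold genes it was -2.50 for DREB2A, -1.14 for COR15B and -0.59 for ABI1. For the antioxidant genes CAT2 and VTC2 it was -2.68 and -1.04, for BCH1 -1.61 and for HSP23.6 -1.25. The clock genes FKF1 (-2.67), ELF4 (-1.39) and TOC1 (-1.55) had the same sign. UGT84A1 and DREB2A involve a group not well above background.

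Among named genes that UV-B lowered at 4 h, the difference was positive for the auxin and growth genes YUC8 (3.12), HAT2 (1.87) and GA20OX1 (1.74), and for AT4G13790 (2.18), AT3G21330 (4.35) and AT4G35720 (2.40). Ethylene genes ACS8 (4.28) and CTR1 (1.04), jasmonate genes ST2A (1.57) and LOX3 (1.31), and salicylate genes WRKY70 (0.96) and EDS1 (1.28) were positive too, as were the actin gene ACT8 (0.75) and SEN1 (1.92). YUC8, AT4G13790, AT3G21330 and ACS8 involve groups not well above background. AT4G14819 and AT5G19190 fell further at 8 h (-1.24 and -1.79). SWEET15 turned from 0.74 at 4 h to -1.79 at 8 h (-2.52), and RAB18 (-0.67) and LNK2 (0.77), not called at 4 h, also differed. The genes named for their difference alone were AT4G18540 (2.60), AT1G61360 (2.52), AT4G30280 (-3.57), AT3G19030 (-3.14), AT4G16740 (-3.14), AT4G30290 (-3.01) and AT3G14395 (-2.95).

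The counts of called genes were set against other splits of the same arrays. At 4 h 1 of the 10 splits of the 6 arrays, the real one, called as many genes (8289, highest other 0). At 8 h it was 1 of 10 (4996, highest other 1) and for time in controls 1 of 10 (3691, highest other 0). With 10 splits the share cannot fall under 0.05. For the mean of both times 1 of 100 splits, the real one, reached 9075 genes (highest other 3872), so such a count was rare among these splits. Most other splits mixed UV-B and control arrays, so a real effect widens the spread there and lowers their counts. For the difference 2 of 100 dealings reached 2076, the real one and another with 3797 genes, a share under 0.05. Only the additive effects of time and treatment were taken out before dealing, so a real difference lowers the counts of mixed dealings too. Because another dealing called more genes than the real labels, chance is not excluded for the difference. The dealing with 3797 genes exchanged the sides of control replicates 3 at 4 h and at 8 h, both on slide 1. Why it called more genes was not tested. FKF1 kept these control groups apart, at most -0.48 at 4 h and from 3.79 to 3.85 at 8 h. Within slide 1 the difference counted 465 genes, with slide as a block 2434, and without control replicate 3 at 8 h 3158.

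Many genes differed under UV-B at both times (8289 and 4996), and 2 technical explanations were tested. With each array's brightness as a covariate, 98.99% of the genes called at 4 h and 93.5% of those at 8 h kept call and direction, which argues against brightness as the whole cause. If the column on slide 1 were the cause, the difference between the slide 2 arrays, all in column 2, would have a slope near 0 on that of slide 1. The slopes were 0.817 (interval 0.809 to 0.824) over 6846 genes at 4 h and 0.832 (0.818 to 0.845) over 3431 genes at 8 h. This argues against the column as the whole cause, though the intervals do not cover dependence between genes. A partial effect of the column stays open. On slide 2 the UV-B arrays lay in rows 1 and 2 and the controls in rows 3 and 4, so an effect of the row there was not tested. On slide 1 the row went with the time: 4 h arrays lay in rows 1 and 2 and 8 h arrays in rows 3 and 4. A response to UV-B is the reading that the design addresses, but it was not tested in other samples. What the replicates were is also not known.

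Of the genes whose effect differed with time, 81.4% had the smaller effect at 8 h. With the brightness covariate the share was 83.2%, with probes well above background on every array 80.4%, and under the other scalings from 81.5% to 85.2%. These values argue against brightness, signals near background and scaling as the cause of that share. They do not cover which genes were called. Of the genes called for the difference, 76.3% kept call and direction with the brightness covariate, 92.1% with the stricter filter and 57.6% under normexp. Array weights gave the lowest share, 70.2%. A weaker response at the later time may be the reason. However, elapsed time, the unclear dose by 8 h, the time of day and the change of the controls with time were not separated.

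FKF1, ELF4 and TOC1 were higher under UV-B at 4 h. They were among the 6 clock genes that rose with time in controls. UV-B plants may therefore have been harvested later in the day than their controls. Over the 532 genes that fell at least 2-fold with time, the median ratio of the UV-B change at 4 h to the time change was 0.309 (quartiles -0.122 and 0.843), against 0.0341 in simulated data without an effect. That is just over the 0.3 set beforehand (252 genes called in the direction of time and 87 in the opposite one). Over the 484 genes that rose at least 2-fold the median ratio was 0.244 (188 and 57 genes, 0.0517 in simulated data). Their quartiles were -0.101 and 0.637, so the lower quartile went against the direction of time. Both changes subtract the same 4 h controls, which the simulation kept, but its noise was independent between genes. A deviation of these controls shared by many genes could raise both ratios and was not simulated. A later harvest stays open. Against it, the 4 clock genes that fell with time had a median change of 0.49 at 4 h, with RVE8 (0.91) and PRR9 (1.24) called higher and LNK2 (0.04) and LNK1 (0.08) not called. An effect of UV-B on the clock was not tested on its own and also stays open.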

How the results depend on the processing

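Of the settings in this part, normexp on the median signal, the brightness covariate, weights fitted gene by gene, and slide 1 alone or each array left out for gene lists were chosen after the data were seen, and the planned normexp on the mean signal was not run because the files hold no such column. Over 73 counts under other settings 62 stayed within 1.5 times the reported one, and with an array left out 30 of 42 did. For counts by direction these were 122 of 146 and 62 of 84, and for 2-fold counts 64 of 73 and 40 of 42. Of 2598 comparisons of named genes 91 lost the call, 2 reversed and the others kept direction and side of the threshold, and 98 of 1146 lost it with an array left out. Named genes were mostly picked for large changes or small adjusted p in the reported setting, which favours keeping the call. Over all called genes, the lowest share that kept call and direction with every array in its group was not as high. In settings other than an array left out it was 75.9% at 4 h, 60.5% at 8 h and 19.9% for the difference. Gene lists stayed called or not called as reported in 570 of 644 (44 lost a call, 30 gained one) and in 644 of 690 (28 lost, 18 gained). Lists called in neither setting count as kept even where their direction changed, as heat shock at 8 h did by fry. The overlap stayed as reported in 12 of 12 comparisons. These covered only the stricter filter, quantile normalization and the replicate number as a block. Counts ran from 6799 to 11527 at 4 h, from 3354 to 8807 at 8 h and from 7638 to 12345 for the mean of both. With only the 6 arrays of a comparison fewer arrays set the spread, and with no filter on dim probes more genes share the adjustment. With an array left out a group of 2 remains. Signal over background limits the folds of genes with a group not above it. Where a value below departs from the reported one and nothing else is said, the cause was not tested.

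Under normexp the difference between times counted 1322 genes (415 higher), and WER (0.013) and CESA8 (0.02) at 4 h reversed their sign. Under the percentile over bright probes 1684 differences were higher. With no filter on dim probes 1777 genes were lower at 8 h, the difference counted 602 (244 higher, 358 lower) and time in controls 2241 (1202 higher, 1039 lower). With array weights the counts were 8807 at 8 h (3653 higher, 5154 lower), 6912 for the difference (2983, 3929) and 7755 for time in controls (4231, 3524). The default fit of these weights stopped before its tolerance, and fitted gene by gene they gave 8132 (3368, 4764), 5978 (2620, 3358) and 5642 (3109, 2533). Within slide 1 the difference counted 465 (168, 297) and time in controls 1718 (854, 864). With only the 6 arrays of the comparison 1803 genes were lower at 8 h.

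With an estimated correlation the calls of these lists ended. At 4 h they were antioxidants (adjusted p = 0.285), clock (0.085), growth (0.285), jasmonate (0.497), photosynthesis (0.681), reference genes (0.285) and UV-B signalling (0.062). At 8 h they were abscisic acid and cold (0.396), clock (0.078), DNA repair (0.158), ethylene (0.078), growth (0.158), photoprotection (0.125), photosynthesis (0.513) and UV-B signalling (0.059). For the difference they were abscisic acid and cold (0.383), antioxidants (0.383), ethylene (0.311) and phenylpropanoids (0.053). For time in controls they were growth (0.587), phenylpropanoids (0.163), photoprotection (0.143), photosynthesis (0.729) and UV-B signalling (0.163).

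By fry, which tests a list against no change and not against other genes, further lists were called. At 4 h these were abscisic acid and cold (0.017), DNA repair (1.0e-05), heat shock (0.012), photoprotection (1.3e-04), salicylate (1.5e-04) and vascular markers (0.0014), while photosynthesis was not (0.097). At 8 h they were glucosinolates (0.015) and reference genes (0.045), and for the difference salicylate (0.044), UV-B signalling (0.0018) and vascular markers (0.044). For time in controls they were clock (0.0054), glucosinolates (0.018), senescence (0.018) and vascular markers (0.045), while photosynthesis was not (0.245).

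Under quantile normalization the calls of abscisic acid and cold at 8 h (0.063) and of antioxidants for the difference (0.517) ended. It added jasmonate (0.022) and reference genes (0.0027) for the difference and cell cycle (0.038) and jasmonate (0.038) for time in controls. With the brightness covariate DNA repair at 8 h (0.051) and antioxidants for the difference (0.056) lost their calls. It added jasmonate (0.021) and reference genes (0.021) for the difference and cell cycle (0.047), glucosinolates (0.037) and jasmonate (0.047) for time in controls. With the replicate number as a block, antioxidants and ethylene for the difference came to 0.052 and 0.052, and with slide as a block to 0.057 and 0.057. Within slide 1 photoprotection at 8 h (0.096), abscisic acid and cold (0.063), antioxidants (0.063) and ethylene (0.122) for the difference and photosynthesis for time in controls (0.065) lost their calls, and glucosinolates for time in controls gained one (0.049).

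With each array left out in turn the difference ran from 848 genes without control replicate 2 at 4 h to 3158 without control replicate 3 at 8 h (358 to 1377 higher, 490 to 1781 lower). It also moved over 1.5 times without control replicate 1 (1215) or UV-B replicate 2 (1024) or 3 (963) at 4 h, and without control replicate 1 (1002) or 2 (1357) or UV-B replicate 2 (1091) or 3 (1079) at 8 h. Time in controls ran from 2022 without control replicate 2 at 4 h to 4219 without control replicate 3 at 8 h (1038 to 2376 higher, 984 to 1843 lower), and was 2346 without control replicate 1 at 4 h and 2386 without control replicate 2 at 8 h. Genes lower at 8 h ran from 1792 without UV-B replicate 2 to 3035 without UV-B replicate 1. The totals at 4 h (6496 to 8079), at 8 h (3362 to 5165) and for the mean of both (7874 to 9338) stayed within 1.5 times.

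For lists with an array left out, adjusted p at 4 h ran from 0.042 to 0.130 for DNA repair and from 0.0065 to 0.085 for jasmonate. At 8 h it ran from 0.0078 to 0.0996 for abscisic acid and cold and from 0.029 to 0.361 for glucosinolates. For the difference the ranges were 0.021 to 0.080 for antioxidants, 0.021 to 0.069 for ethylene, 0.0051 to 0.155 for jasmonate, 0.037 to 0.917 for photosynthesis and 0.036 to 0.240 for reference genes. For time in controls they were 0.029 to 0.227 for cell cycle, 0.044 to 0.189 for glucosinolates, 0.0045 to 0.199 for growth, 0.015 to 0.184 for jasmonate and 0.0012 to 0.054 for phenylpropanoids. For photosynthesis they were 0.0028 to 0.331, and for UV-B signalling 0.0075 to 0.072.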

Other observations

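The 4 gene groups in this part, and every test on them, were chosen after the results were seen. Of 21 small auxin-up RNA genes, which auxin induces, 14 fell and 1 rose at 4 h, with a median of -1.52, or -1.59 with genes not above background at their bound or left out. SAUR65 fell by 3.61 ± 0.22, SAUR23 by 3.21 ± 0.21 and SAUR27 by 2.81 ± 0.18, while SAUR59 rose by 0.66 ± 0.14. At 8 h 12 fell and 1 rose, with a median of -1.07. SAUR65 fell by 3.53 ± 0.22 and SAUR64 by 2.88 ± 0.16, while SAUR9 rose by 1.55 ± 0.20. Camera called the group at 4 h (adjusted p = 2.5e-06) and at 8 h (adjusted p = 6.4e-09), but not with an estimated correlation (adjusted p = 0.193 and 0.095). In controls 10 fell and 3 rose with time, with a median of -0.55 (adjusted p = 0.0016, or 0.415 with an estimated correlation). For the difference between times 2 were higher and 3 lower, with a median of 0.14 (adjusted p = 0.60).

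Genes that make chorismate and phenylalanine, the substrate of the flavonoid pathway, rose in 7 of 9 cases at 4 h and fell in 0, with a median of 1.297. CM1 rose by 3.62 ± 0.11, the arogenate dehydratase genes ADT3 and ADT4 by 4.12 ± 0.25 and 3.83 ± 0.16, and DHS3 by 1.72 ± 0.15. At 8 h 6 rose and 0 fell, with a median of 1.15, and ADT4 rose by 2.50 ± 0.16. The group was called at both times (adjusted p = 2.2e-06 and 1.2e-07), also with an estimated correlation (adjusted p = 0.029 and 0.019). Its difference between times was called, with 3 of 9 genes lower, 0 higher and a median of -0.26 (adjusted p = 0.030). That call ended with an estimated correlation (0.376), under quantile normalization (0.269), without UV-B replicate 2 at 4 h (0.069) and without control replicate 3 at 8 h (0.117). In controls 3 rose with time and 0 fell, with a median of 0.21 (adjusted p = 0.051). The group was called there by fry (0.0088), with the brightness covariate (0.048), and without control replicate 3 at 4 h (0.049) or control replicate 1 (0.036) or 2 (0.031) at 8 h.

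Tau class glutathione transferase genes went both ways. At 4 h 2 of 9 rose and 3 fell, with GSTU18 at 1.54 ± 0.13 and GSTU3 at -1.35 ± 0.25, and a median of -0.33 that became 0.16 under normexp (adjusted p = 0.78). At 8 h 1 rose and 2 fell, with a median of -0.42 (adjusted p = 0.61). The difference had 1 gene lower and a median of -0.13, or 0.03 under the percentile over bright probes (adjusted p = 0.60), and time in controls 1 higher and 1 lower with a median of 0.06, or -0.01 under that scaling (adjusted p = 0.94). Of 37 plastid genes, counted by gene model and not by locus, 0 were called at 4 h (median 0.15, adjusted p = 0.12). At 8 h 1 was higher (median 0.03, adjusted p = 0.61). Neither the difference (0 called, median -0.25, adjusted p = 0.53) nor time in controls (0 called, median 0.09, adjusted p = 0.94) gave a call. Plastid genes were called within slide 1 at 4 h (adjusted p = 0.013) and for the difference (0.033), at 4 h without UV-B replicate 1 (0.038), and at 8 h under quantile normalization (0.015).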
